A study of Caenorhabditis elegans with 2 samples.

How the data were processed

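Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole *C. elegans* L4 larvae of mixed sex that carried an integrated eGFP fusion of lsy-2, in 2 biological replicates per the labels. The deposited files used here were peak lists in narrowPeak format without header lines. They comprised a list of candidate peaks and background regions for each replicate, a candidate list from both replicates pooled, and an "optimal" list kept after thresholding on the irreproducible discovery rate (IDR), per the deposited text listings. The listings derive the candidate lists from immunoprecipitation and control alignments. The aligner, the peak caller and the IDR threshold were not given in the sources used here. Each list was deposited on the ce11 and ce10 builds. The signal value of each peak is the authors' own, as deposited, and the lists of the 2 replicates have separate scales, so signal was used to rank and describe peaks. The deposited -log10 q values reached a ceiling of 3.53 in the pooled candidate list, and 1695 pooled candidates sat at it. The p column of the deposited lists was not filled. Read numbers were not given in the files used, so depth is unknown and no interval here covers it.

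The optimal ce11 list was identical to the 1563 strongest pooled candidates, down to a signal of 60.3. The ce11 build is the WBcel235 assembly of the reference, and all peaks fell within its chromosomes, so genes came from Ensembl release 115 and sequence from the RefSeq copy of the same assembly. The ce10 lists served as an alternative for counts and replicate overlap, and no coordinates were converted. Coordinates are 1-based. A gene was called bound when a summit of the optimal list lay within 500 bp of an annotated transcript start, and 19973 protein-coding genes formed the background. Summits outside those windows were assigned in order to coding exons, other exons of protein-coding genes, introns, noncoding genes or pseudogenes other than piRNA genes, and intergenic sequence.

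Observed overlaps were compared with 1000 random placements of the peaks within their own chromosomes (one-sided permutation test). The smallest p these placements can give is 0.001. Replicates were compared by the overlap, by at least 1 bp, of the 1563 strongest candidates of each, by Spearman and Pearson correlation of log2 signal across peaks with a bootstrap interval from 1000 resamples, and by a Gaussian copula IDR fit on mutually matched candidates. Peaks are not independent replicates, and no p was computed for the correlations. The shares of peaks on chromosome X and in the middle 50% of each autosome were tested against the shares of protein-coding genes with two-sided exact binomial tests. The 27 gene lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the lists. Noncoding gene classes with at least 10 genes were tested by placement with a window of 200 bp and adjusted over 6 classes. Median log2 signal at and away from transcript starts was compared with 100000 permutations, two-sided. All 2080 6-mers, each counted together with its reverse complement, were compared between 101 bp windows centred on summits and equal windows centred 500 bp to either side with two-sided Fisher's exact tests. Peaks within 20 kb of lsy-2 were counted beside those at 1000 random protein-coding genes. Confidence intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only.

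The tests, the 27 gene lists and the alternatives were fixed before the data were examined, except where stated. The named genes were the 25 met first when the optimal peaks with a candidate in both replicates were read from the highest signal down, by nearest protein-coding start within 500 bp. They also included lsy-2, lsy-6, che-1, cog-1, die-1, lim-6 and unc-119 in every case, up to 3 bound members of each list by signal, and up to 3 tRNA and miRNA genes with the strongest peak within 200 bp. The alternatives were the ce10 lists, the 781 strongest peaks, the strongest candidates of either replicate alone, stricter or looser overlaps, other windows around starts, other reference shares and backgrounds, nearest-gene assignment, other 6-mer backgrounds, IDR thresholds of 0.02 and 0.01, and windows of 10 kb and 40 kb around lsy-2. A background of genes with a locus-type symbol was added after the data were seen. Also outside the planned tests were the signal of ribosomal protein peaks, the bound share of genes on X against autosomes, and the X shares of peaks at and away from starts.

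The procedures were tested on simulated data. Of 100 random peak sets, 4 had a placement p at or under 0.05. Random sets of bound genes gave 5 false list calls over 100 sets. Those genes were drawn independently, whereas real bound genes can share a peak. With a strong excess planted in each of the 24 larger lists in turn, 22 were called. Smaller lists and weaker excesses were not simulated, so a list that was not called may still differ from other genes. No 6-mer was called where none was planted, in simulated windows of equal base composition. Real summit windows had 47.7% GC and flanks 36.5%, a difference that the simulation left out. At an IDR of 0.05 the fit kept 88.2% of simulated reproducible peaks, with 4.55% of those kept being unreproducible. The simulated pairs came from the mixture that the fit assumes, with unreproducible peaks independent between replicates. Real matched candidates outside the strongest of both replicates were still correlated (Spearman 0.327), so these rates need not hold for the real lists. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Read-level files and signal tracks were not analysed here.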

Results

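LSY-2 is a C2H2 zinc finger protein that acts in the left ASE taste neuron, where it is required for expression of the microRNA lsy-6. The immunoprecipitation targeted an eGFP-tagged copy of LSY-2 in whole L4 larvae, with 1 group of 2 biological replicates and no second condition to compare. The data addressed where the tagged protein lay on the genome at this stage. The optimal list held 1563 peaks covering 560.04 kb, and the candidate lists held 25003 regions in replicate 1 and 24002 in replicate 2. Sequencing depth is unknown for both replicates.

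The highest signal, 7029, was at rpl-3 (WBGene00004414, chromosome III, 3867854 to 3869587 on ce11), which encodes a protein of the large ribosomal subunit, with the summit 282 bp upstream of the transcript start. The same peak had the highest signal in each replicate, 3100 in replicate 1 and 3946 in replicate 2. Next came a peak with a signal of 5056 between the divergent genes Y17G9B.5 and rpl-20, then rpl-15 at 4423, the small-subunit gene rps-1 at 3828 and the cytochrome c oxidase gene cox-5A (WBGene00012553, chromosome III, 12905491 to 12906619) at 3655.

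The 25 genes named by signal had values down to 885 at rpl-35. Ribosomal protein genes were 5 of them, with rpl-11.2 on chromosome X at 1065. Respiratory genes were 3, with the second cytochrome c oxidase gene cox-5B at 1612 and the ATP synthase gene atp-1 at 1194. The synMuv B and DREAM genes lin-53, which encodes a histone-binding protein, and lin-9 had signals of 1713 and 1219. Others included the elongation factor gene eef-2 (1085), the AAA ATPase gene cdc-48.1 (1058), the Dishevelled gene mig-5 (1704), the actin-capping gene cap-2 (1957), the COPII coat gene sec-24.1 (916) and serp-1.1 on chromosome X (2700.2). The rest were F55A11.1, Y55F3AR.2, Y25C1A.8, ekl-4, frg-1, T26A8.4, tasp-1 and tmem-107, besides Y17G9B.5. All 25 peaks ranked within the first 100 of both replicates' own lists. Only 1 of the 26 strongest peaks had no protein-coding start within 500 bp. It lay on chromosome III from 9765156 to 9765937, 0.904 kb from the nearest start, that of cbp-1, which encodes a CBP/p300 acetyltransferase, and this gene was named after its value was seen.

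**Figure D1:**
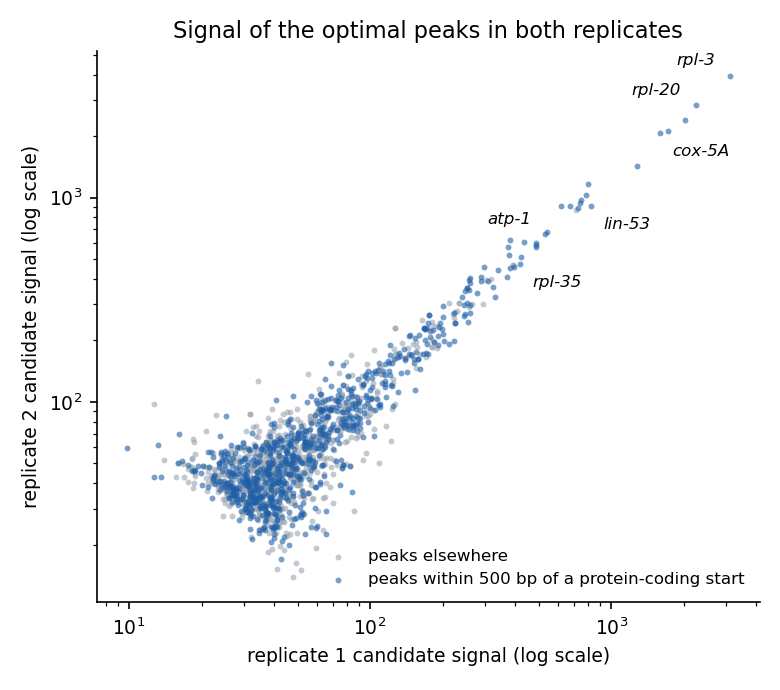
Signal of each optimal peak in the strongest overlapping candidate of replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), with peaks within 500 bp of a protein-coding transcript start in blue and the others in grey. The strongest peaks, led by rpl-3 at 3100 and 3946, lie close to a line, and the spread widens towards low signal.

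Ribosomal protein genes had the highest bound share of the 27 lists. A peak lay at the start of 58 of 81 (71.6%, 95% exact interval 60.5 to 81.1%), against 4.50% of other protein-coding genes, an odds ratio of 53.5 (Fisher's exact test, adjusted p = 4.12e-57). Both subunits were involved, with 35 of 47 rpl genes and 23 of 31 rps genes bound. Their peaks were also stronger than those at other starts, with a median signal of 244.7 against 92.8 (2.64-fold, permutation p = 1e-05, the smallest possible with 100000 permutations). This comparison was not among the planned tests, and ribosomal protein genes already led the ranking by signal. Its p is therefore no independent test, and peaks are not independent replicates.

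Genes for other core cell functions were bound more often as well. Of 30 spliceosome and SR protein genes 12 were bound (odds ratio 13.4, Fisher's exact test, adjusted p = 4.62e-08), led by the splicing factor genes rsp-6 (539), prp-8 (387) and rsp-5 (303). Of 38 respiratory chain and ATP synthase genes 12 were bound (odds ratio 9.31, adjusted p = 6.08e-07 by the same exact test). Chaperone genes had 15 of 57 bound (odds ratio 7.22, exact test, adjusted p = 3.11e-07), and the strongest were the chaperonin genes cct-1 (1704) and cct-8 (1675) and the J-domain gene dnj-14 (407). The cct-1 and cct-8 peaks are the same peaks as those of mig-5 and Y55F3AR.2, whose starts lie nearer. With each peak given to its nearest gene alone, 8 of 57 chaperone genes were bound (odds ratio 4.19). Proteasome genes had 8 of 33 bound (odds ratio 6.43, exact test, adjusted p = 0.000397), including pas-4 (463), rpn-5 (353) and rpn-3 (274).

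Lists of chromatin, cell cycle and developmental timing regulators were also bound more often than other genes. In the synMuv B and DREAM list, 6 of 18 genes were bound (odds ratio 10.02, Fisher's exact test, adjusted p = 0.000397), with lin-54 at 332 after lin-53 and lin-9. Of 52 DNA replication and cell cycle genes 8 were bound (odds ratio 3.65, exact test, adjusted p = 0.00688), among them the clamp loader gene rfc-4 (676), cdk-7 (164) and the origin recognition gene orc-1 (118). Of 13 heterochronic genes, which time larval development, 4 were bound (odds ratio 8.89, exact test, adjusted p = 0.00642). The 3 strongest were the Pumilio family gene puf-9 (310), the RNA-binding protein gene lin-28 (130) and lin-42 (67.1).

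Large families of sensory, defence and degradation genes were bound less often than other genes. Only 4 of 1360 chemoreceptor genes had a peak (0.294%, Fisher's exact test, adjusted p = 4.16e-23), with srh-2, sri-5 and srh-16 the strongest at 149.5, 87.4 and 68.7. The counts were 1 of 332 for innate immune effectors (clec-126, adjusted p = 1.32e-05 by exact test) and 3 of 388 for F-box, MATH and BATH genes (fbxb-72, fbxb-85 and fbxc-23, adjusted p = 6.63e-05 by exact test). They were 1 of 185 for detoxification enzymes (cyp-13A2, adjusted p = 0.00642 by exact test) and 1 of 140 for neuropeptides (nlp-4, adjusted p = 0.0322 by exact test).

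The lists for differentiated tissues and the germline did not pass the test in the main analysis. With a window of 1000 bp upstream to 200 bp downstream, pan-neuronal genes were called higher (odds ratio 4.29) and cuticle collagens lower (0.189). Collagens were also called lower (0.263) with the 500 bp window when only genes with a locus-type symbol formed the background, an alternative chosen after seeing the data. Bound genes were 3 of 24 pan-neuronal genes (syd-2, ric-19 and egl-21), 2 of 28 muscle genes (unc-112 and unc-60), 3 of 173 cuticle collagens (col-38, col-72 and col-176) and 0 of 20 intestinal genes. They were 0 of 26 vulval development genes, 2 of 19 molting genes (myrf-1 and nhr-25), 9 of 274 nuclear hormone receptors (nhr-1, nhr-49 and nhr-40 the strongest) and 3 of 94 homeobox genes (ceh-38, unc-62 and unc-30). Germline lists gave 1 of 35 meiosis genes (brc-1), 1 of 41 P granule and germline RNA regulators (ekl-1) and 0 of 31 major sperm protein genes. Histone genes had 1 of 50 bound (his-37) and aminoacyl-tRNA synthetase genes 3 of 32 (ears-2, kars-1 and mars-1). With 0 of 20 intestinal genes bound, a share of up to 16.8% was within the exact interval.

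In all, 13 of the 27 lists were called, 8 higher and 5 lower. With genes that had a candidate peak as the background, 8 lists were called, and the calls for proteasome, heterochronic, DNA replication and cell cycle, F-box and neuropeptide genes ended. The odds ratio of ribosomal protein genes was 18.99 against that background and 8.44 with a 250 bp window, where 16 of 81 were bound. The DNA replication and cell cycle, heterochronic and neuropeptide calls also ended with the 781 strongest peaks and with a 250 bp window. That window ended the detoxification call too, and nearest-gene assignment the neuropeptide call.

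**Figure D2:**
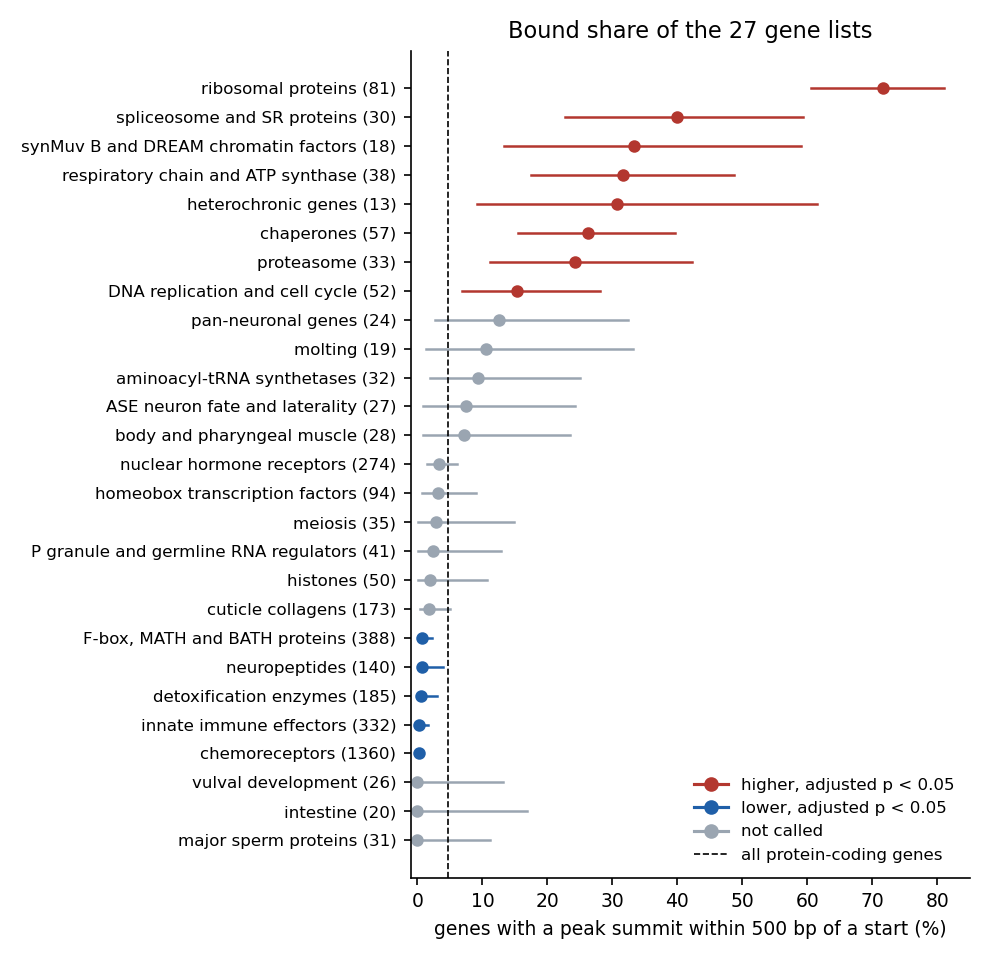
Share of each gene list with a summit within 500 bp of a transcript start (x axis, percent; points) with 95% exact intervals (lines) and list sizes in parentheses. Red lists were bound more often and blue lists less often than other genes at an adjusted p under 0.05, grey lists were not called, and the dashed line marks the 4.78% of all protein-coding genes. Ribosomal proteins lie highest at 71.6%.

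Transcript starts of protein-coding genes were the main location. Summits of 779 peaks (49.8%, 95% exact interval 47.3 to 52.3%) lay within 500 bp of a start, against 22.8% under random placement (permutation p = 0.001, the smallest possible), and 954 genes (4.78%) were bound. Within 250 bp the shares were 32.4% and 12.1%. Of these 779 summits, 695 (89.2%) lay upstream of the nearest start, with a median position of -178 bp and quartiles of -278 and -76.0 bp. Coding exons held 1.02% of summits against 18.03% under placement, and introns held 13.8% against 27.2%. Intergenic sequence held 28.3% against 25.7%, untranslated exons 2.75% against 2.97%, and noncoding genes or pseudogenes 4.29% against 3.42%.

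Peaks at starts were stronger than those elsewhere, with median signals of 95.4 and 86.05 (a log2 difference of 0.15, permutation p = 0.00021), and among the 781 strongest peaks the difference was 0.31. The share at starts was 61.6% among the strongest 391 peaks and 43.7% among the weakest 391.

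**Figure D3:**
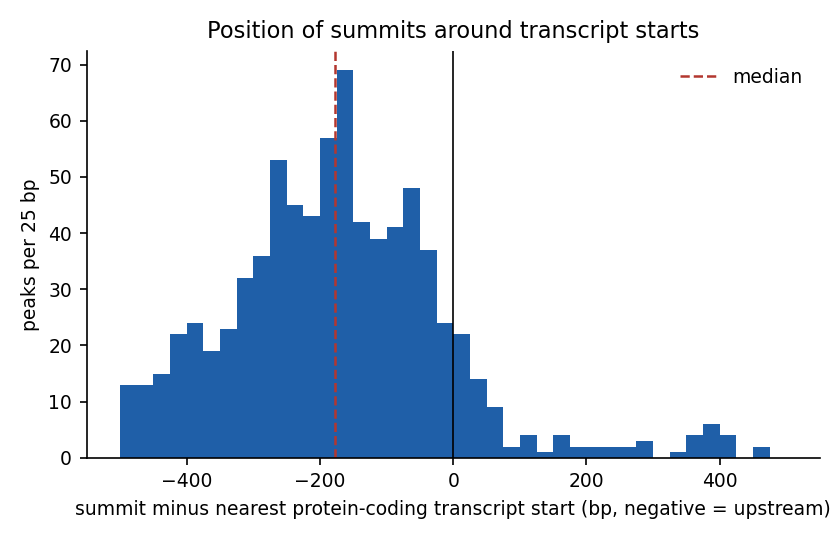
Position of the summit relative to the nearest protein-coding transcript start (x axis, bp, negative upstream) for the 779 peaks within 500 bp, counted per 25 bp (y axis). The dashed line is the median of -178 bp, and 89.2% of summits lie upstream of the start.

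By the share of protein-coding genes bound, chromosomes I and III were highest and chromosome V lowest. Bound genes were 7.23% of protein-coding genes on chromosome III, 7.09% on I, 4.79% on IV, 4.73% on II, 3.95% on X and 2.62% on V. Chromosome X held 270 peaks (17.3%, 95% exact interval 15.4 to 19.2%) against 13.7% of protein-coding genes (exact binomial p = 5.87e-05). Relative to the gene share, this excess lay in peaks away from starts. X held 13.2% of the peaks at starts and 21.3% of the others. Against its 17.7% of genome length, the exact binomial p for the others was 0.00872. That length includes the windows around starts, where these peaks cannot lie, so no excess over available sequence is read from it. Against that share of length, or its 19.04% share of pooled candidates, the X share of all peaks was not higher. Counted by genes, 108 of 2731 on X were bound, less often than the 4.91% on autosomes (odds ratio 0.798, Fisher's exact p = 0.0297). The middle 50% of the autosomes held 826 of 1293 autosomal peaks (63.9%) against 55.7% of genes (exact binomial p = 1.96e-09), although pooled candidates were as central (63.1%, exact binomial p = 0.584).

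**Figure D4:**
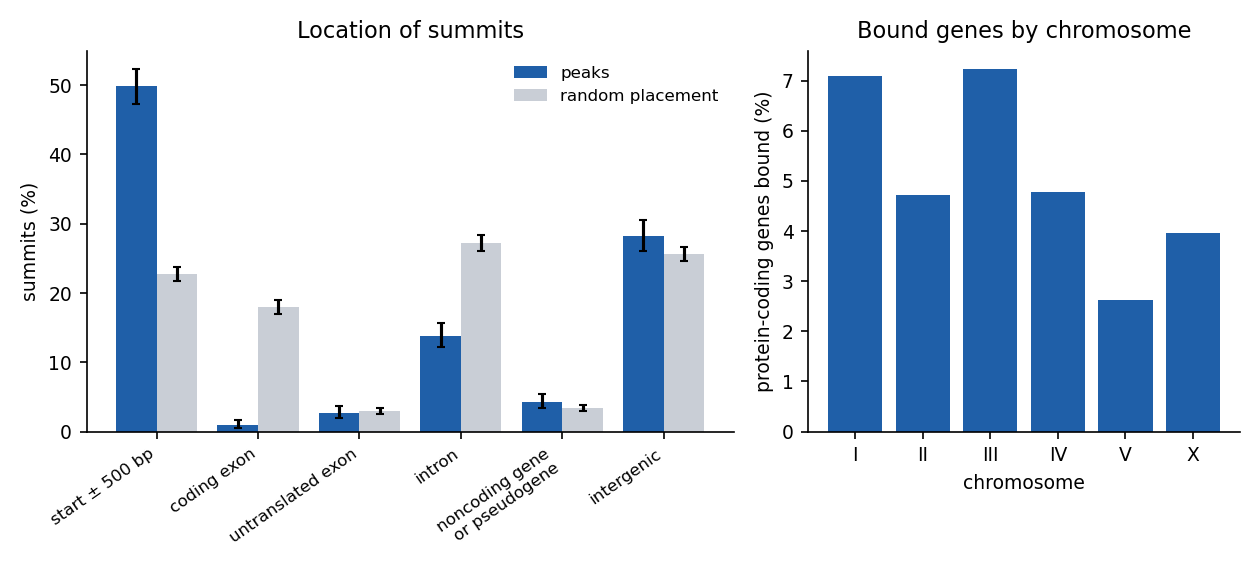
Left, share of optimal summits (percent, blue, 95% exact intervals) and of randomly placed peaks (grey, mean with SD over 1000 placements) in each part of the genome, assigned in order from left to right. Right, percent of protein-coding genes bound on each chromosome. Starts hold 49.8% of summits, and chromosomes I and III exceed 7% of genes.

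Genes for several short noncoding RNAs also had peaks nearby. Within 200 bp, snRNA genes met 18 peaks (18.9 times the number under placement), snoRNA genes 35 (11.8 times), tRNA genes 32 (7.66 times) and miRNA genes 7 (3.65 times). The permutation p adjusted over 6 classes was 0.003 for miRNA genes and 0.002 for the other 3, the latter from the smallest p that placement can give. Placement was uniform along each chromosome and did not keep the preference of peaks for protein-coding starts. How much of these ratios that preference gives was not tested. Whether other tagged factors also give peaks at these genes was not tested either. The ratios depended on the setting, with 10.3 for snRNA and 3.88 for tRNA genes but 5.41 for miRNA genes within 500 bp, and 4.12 for tRNA genes among the 781 strongest peaks. The strongest tRNA-linked peak, with a signal of 198.3, overlapped WBGene00023117 on chromosome X (410391 to 410462), and a peak of 129.3 lay at WBGene00023050 and WBGene00023051 on the same chromosome. The miRNA genes with the strongest peaks were mir-5549 (676), which shares its peak with the start of rfc-4, then mir-52 (171.5) and mir-56 (141.3). No peak lay at any of the 20 rRNA genes, but placement put a mean of only 0.0163% of the 1563 peaks there, so this absence shows little. The piRNA genes met 13 peaks, 0.284 times the number under placement.

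The same regions recurred in both replicates, most of all at the strongest genes. Among the 1563 strongest candidates of replicate 1, 1097 (70.2%) were overlapped by those of replicate 2, against 1.18% under placement (permutation p = 0.001, the smallest possible). Of the 1563 optimal peaks, 1093 (69.9%) were overlapped by the strongest candidates of both replicates, and because that list comes from the pooled replicates, part of this overlap is built in and placement is no null for it. Of the first 100 candidates of replicate 1, 92 were among the first 100 of replicate 2. Across the 1560 optimal peaks with a candidate in both, signal had a Spearman correlation of 0.674 (95% bootstrap interval 0.638 to 0.708) and a Pearson correlation of 0.855 on the log2 scale. These correlations are across peaks, which are not independent replicates. The IDR fit on 11120 matched candidate pairs kept 2214 peaks at 0.05, 1754 at 0.02 and 1491 at 0.01. Those kept at 0.05 overlapped 95.8% of the optimal list, an overlap also partly built in by the pooling of the replicates.

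GA-rich sequence and a CTGCGT element marked the summits. GAGAGA (or TCTCTC) lay in 465 of 1563 summit windows (29.8%) against 5.63% of flanking windows (odds ratio 7.10, Fisher's exact test, adjusted p = 9.95e-104). ACGCAG (or CTGCGT) lay in 18.7% against 2.46% (odds ratio 9.10, exact test, adjusted p = 1.03e-76), and CGTCTC in 20.8% against 3.74% (odds ratio 6.75, exact test, adjusted p = 1.43e-71). AT-rich 6-mers were scarcer at summits, with AAAAAT in 18.4% of summit windows and 47.3% of flanks. Of 2080 6-mers, 665 were more frequent at summits and 531 less frequent, and mean GC content was 47.7% at summits and 36.5% in flanks. Against dinucleotide-shuffled copies of the summit windows, which keep base composition and all dinucleotide counts, 251 6-mers were higher, of which 187 were among the 665. The odds ratio of GAGAGA was then 2.44 and that of ACGCAG 3.90, and with flanks 200 bp away they were 3.10 and 6.48.

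None of the genes of the lsy-6 pathway named in advance had an optimal peak at its start. The nearest optimal summit was 30.3 kb from lsy-6 (chromosome V, 10647232 to 10647304), 33.8 kb from che-1, 107 kb from cog-1, 30.8 kb from die-1 and 8.22 kb from lim-6. Each of these genes acts in the fate or asymmetry of the ASE neurons. Single weak candidates lay within 500 bp of che-1 in replicate 1 only (rank 4255) and of cog-1 in replicate 2 only (rank 23926), and die-1 had candidates in replicate 2 (best rank 7051) and the pooled list (rank 15384) but not in replicate 1. Of 27 ASE fate and laterality genes, 2 were bound, lin-49 (81.6) and the Groucho gene unc-37 (64.5), which did not differ from other genes (Fisher's exact test, adjusted p = 0.517). Whole larvae were used at an unknown depth, and whether a site occupied in a few cells would be detected was not tested.

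No optimal peak lay within 20 kb of the tagged gene, lsy-2 itself, on chromosome X (2089704 to 2093256), or within 500 bp of unc-119, the gene mutated in this strain's background. A count of 0 within 20 kb was also found at 59.8% of 1000 random protein-coding genes. The nearest optimal summit was 147.7 kb from lsy-2 and 53.6 kb from unc-119. Among candidates, 5 of the pooled list lay within 20 kb of lsy-2, the strongest at rank 5340. In replicate 1 the strongest had rank 1226, within its 1563 strongest candidates, and in replicate 2 rank 12502.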

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

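This comparison was chosen after the lists were seen. The candidates ranked below the 1563 strongest of each replicate were not compared on their own in the report. Of the 23440 in replicate 1, 45.7% were overlapped by those of replicate 2, against 15.96% under random placement. No p is given, since it would restate the excess that drew attention to these candidates. What drew attention was this overlap in data that the report left uncompared. Among 9195 matched pairs of such candidates the Spearman correlation of signal was 0.327. This is not set against the value for the optimal peaks, since a narrower range of signal lowers a correlation by itself.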

How the results depend on the processing

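Of 61 alternatives to the main results, 54 were labelled the same. For tests this meant the same direction and call. Counts had to stay within 1.5 times the main count, and correlations within the bootstrap interval. A count with that label could still hold fewer calls, as with 9 lists against 13 in the 250 bp window. The share on chromosome X, 3.601 percentage points above the gene share, was -0.396 points from the share of length and -1.76 points from that of pooled candidates, since those references are higher. The excess of the autosomal middle fell to 0.749 points against pooled candidates. Signal correlation was 0.769 over the 781 strongest peaks, which leaves out the weak peaks. Gene lists called numbered 8, against 13, with genes that have a candidate as background, where fewer genes were tested. Enriched 6-mers numbered 251, against 665, with shuffled windows, and 187 were in both sets. Peaks near lsy-2 numbered 0 without replicate 1 and 1 without replicate 2. The other alternatives for replicate overlap, transcript starts, noncoding classes and signal kept their calls. Of 214 values for single lists, 185 were the same, 13 lost the call, 3 gained it and 13 changed direction, all of the last in lists not called in the main analysis. The DNA replication and cell cycle, heterochronic and neuropeptide calls ended with the 781 strongest peaks, with a 250 bp window and with the candidate background, and the neuropeptide call also with nearest-gene assignment. Calls gained were pan-neuronal genes (1000 bp upstream to 200 bp downstream) and cuticle collagens (that window and the locus-type background). Ribosomal protein, spliceosome, chaperone, respiratory, synMuv B and DREAM, chemoreceptor and innate immune calls held in every alternative run, though their odds ratios varied. The ranges were 8.44 to 50.4 for ribosomal proteins, 5.78 to 17.9 for spliceosome, 3.79 to 11.7 for chaperone and 4.24 to 11.1 for respiratory genes. They were 6.33 to 12.96 for synMuv B and DREAM, 0.0241 to 0.263 for chemoreceptor and 0 to 0.0995 for innate immune genes. Odds ratios that changed direction were 0 for ASE, muscle and molting genes and 1.03 for meiosis (781 strongest peaks), 0 for muscle and 1.10 for homeobox genes (250 bp), 1.76 for P granule genes (1000 bp upstream to 200 bp downstream) and 0.874 for muscle (candidate background). Without replicate 1 or 2, odds ratios ranged from 0.786 to 1.68 for ASE, 0.427 to 1.31 for histones, 0 to 1.08 for intestine, 0 to 2.41 for molting and 0.709 to 1.02 for nuclear hormone receptors. Except where a reason is given, the cause was not tested. A list of the strongest pooled candidates was identical to the optimal list, so that alternative gave no value. The background of locus-type symbols, chosen after seeing the data, called 14 lists. Unknown depth limits what the absence of a peak can show.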

Other observations

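Chosen only after their results were seen were the background of locus-type symbols, the question of open promoters, the sequences at ribosomal protein peaks, the assembly of CTGCGTCTC, its sharing of summits with GAGAGA, and the chromosome X shares of sequences and weaker candidates. Gene families outside the 27 lists extended the picture of core cell functions, in a test of 8 families chosen after the lists had been seen but before their own counts were, although eef-2 was already known to be bound. Higher bound shares were found in 5 of the 8, in keeping with the idea that genes used in most cells carry these peaks. Of 39 translation factor genes 12 were bound (odds ratio 8.96, Fisher's exact test, adjusted p = 1.25e-06), led by eef-2 (1085), eef-1A.1 (676) and iff-2 (532). Vacuolar ATPase genes had 6 of 20 bound (adjusted p = 0.00102, exact test), with vha-1 at 295, ubiquitin-conjugating enzymes 5 of 21 (adjusted p = 0.00704, exact test), RNA polymerase II genes 3 of 12 and mitochondrial ribosomal protein genes 8 of 70 (both adjusted p = 0.029, exact test). Nuclear pore genes (2 of 26), tubulins (1 of 13) and kinesins (1 of 13) were not called, although npp-3 had a strong peak (653). The RNA polymerase II gene rpb-3 and the proteasome gene pas-4 had the identical signal of 463.444, so the 2 most likely share 1 peak. That peak then counts for the proteasome list and also for 1 of the 3 bound RNA polymerase II genes. No nearest-gene or candidate-background values are given for these 8 families.

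Shared upstream regions were common among the bound genes. The summit of 1 peak at chromosome III (6971937 to 6972262) lay within 500 bp of the starts of rfc-4 and eef-1A.1, and the peak covered mir-5549. Of the 779 peaks at starts, 25.2% had starts on both strands within 500 bp, against 12.97% at random starts sampled at the same distances and at most 16.7% in 1000 samples (permutation p = 0.001, the smallest possible). Peaks at divergent gene pairs were thus more frequent than at starts in general, and whether both genes of a pair respond to LSY-2 was not measured.

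The odds ratio of GAGAGA at summits fell from 7.10 to 2.44 against dinucleotide-shuffled copies. Those copies keep the dinucleotides that GAGAGA itself adds, so the fall cannot tell how much base composition accounts for. Dinucleotide composition alone does not give the excess that remained. Leaving out windows with a tandem repeat of at least 20 bp, 26 at summits, left the odds ratio at 6.97, so long simple repeats are not the source. Starts of genes with no candidate peak carried GAGAGA in 5.70% of windows against 24.3% of the peaks at starts (odds ratio 5.30, Fisher's exact test, p = 8.96e-52). GAGAGA was therefore not equally frequent at all promoters. These control starts lacked even a weak candidate, so a feature of promoters open in most cells was not excluded. No biological explanation was tested, and which protein recognises the sequence stays open.

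Ribosomal protein genes had an odds ratio of 53.5. Giving each peak to its nearest gene alone left 18.3, and restricting the background to genes with locus-type symbols left 41.5, so neither shared upstream regions nor better-studied genes are the whole cause. Recovery of promoters open in most cells with any tagged factor cannot be told apart from LSY-2 binding, because no mock or other-factor list was analysed here to set beside the 71.6% bound. Aminoacyl-tRNA synthetase genes, also used in most cells, were bound at 9.38%. No biological explanation was tested.

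The peaks away from protein-coding starts, 784 in number, recurred in the replicates almost as often as those at starts. The strongest candidates of both replicates overlapped 68.4% of the peaks away from starts and 71.5% of the peaks at starts. The difference was 3.13 percentage points (95% normal interval -1.41 to 7.68). Both groups come from the list made from the pooled replicates, so part of this recurrence is built in. Unreliable calls are therefore not excluded as a source of the peaks away from starts. Starts of noncoding genes lay within 200 bp of 24.2% of the peaks away from starts (95% exact interval 21.3 to 27.4%), so most of these peaks were not near one. No share under random placement was computed here, so how far the 24.2% exceeds placement is unknown. What these sites do was not tested and stays open.

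Overlapping 6-mers at the summits joined into CTGCGTCTC, which lay in 9.02% of summit windows and 0.384% of flanks. It was about as frequent at starts (8.86%) as elsewhere (9.18%, odds ratio 0.961, 95% exact interval 0.669 to 1.38, Fisher's exact p = 0.86), whereas GAGAGA was less frequent at starts (24.3% against 35.2%, exact p = 2.47e-06). The idea that CTGCGTCTC sorts peaks by location therefore found no difference above 1.5-fold in odds. Both sequences tended to share summits, since 50.4% of windows with CTGCGTCTC also held GAGAGA against 27.7% of the others (Fisher's exact p = 7.21e-08). The strings can overlap by several bases, so part of this sharing is built in.

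The ribosomal protein peaks, stronger in the median than the other peaks at starts, seldom held GAGAGA or the full CTGCGTCTC. GAGAGA or CTGCGTCTC lay at 9.09% of their 55 peaks against 31.4% of the 724 other peaks at starts (Fisher's exact p = 0.000204), and CTGCGTCTC at 0 of 55. The shorter ACGCAG (or CTGCGT) was as frequent there (20.03% of the others and 11 of the 55, exact p = 1). The comparison of GAGAGA or CTGCGTCTC was chosen after its counts were seen, so its p is no independent test. Most of the ribosomal protein summit windows held neither string, and binding through the CTGCGT element stays open. CACTCG lay at 32.7% of the ribosomal protein peaks against 5.66% of the others (Fisher's exact test, adjusted p = 1.88e-05), among 46 6-mers that were higher.

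On chromosome X, GAGAGA lay at 39.8% of the peaks at starts against 21.9% on autosomes (Fisher's exact p = 0.000181), though over all peaks the shares were 32.96% and 29.1% (exact p = 0.214). Away from starts the order was the other way, with 28.7% on X and 36.95% on autosomes (exact p = 0.055). A generally higher GAGAGA content of X promoters found little support among starts without a candidate peak, which had an odds ratio of 1.204 (6.95% against 5.84%). The X share of candidates below the optimal list was 19.2% against 17.3% within it (exact p = 0.0661), a difference that these counts cannot settle.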
